A study of Mus musculus with 4 samples.

How the data were processed

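Total RNA of whole retina from C57BL/6J mice at postnatal day 18 was sequenced as 4 bulk libraries, 2 from wild-type mice and 2 from mice labelled Mll5 knockout. Per the labels' protocols, each library was built from RNA of a mixture of 2 eyeballs of female mice, extracted with a column kit. The labels do not say whether the eyeballs of a library came from a single animal, so the p-values measure the spread between these libraries. Y-linked transcripts were present in a library of each group although the labels give female mice. Mll5 is the older name of Kmt2e, under which the deposited tables list the gene.

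The deposited tables give, for each of 35275 genes, a raw read count per library and an FPKM value. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.12 and counted with HTSeq 0.6.1, and the notes name the builds mm9 and mm10. The coordinates in the deposited tables are those of mm10: of 34490 genes found by identifier in a mm10 annotation, 99.9% overlapped the gene of that identifier and 72.3% had its exact start and end. The strand setting of the counting and the treatment of reads with several matches are not given in the sources used here, so genes that overlap an antisense partner or have near-identical copies carry an added uncertainty. The authors' FPKM values scale the deposited counts by the library total and a gene length. For 46.9% of the genes with such a length it equals the length listed beside the gene, within a relative tolerance of 0.0001, and for 53.1% it is shorter. A further FPKM column for the group is deposited for each library. It entered no comparison of the groups, and the reads recovered from it were examined separately, after the data were seen.

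The counts totalled 49577833 and 37744857 reads in wild-type replicates 1 and 2, and 44515931 and 37997381 reads in labelled-knockout replicates 1 and 2. A single read was worth 0.0202 to 0.0265 CPM (reads of a gene scaled to the library total). Replicates of a group were not copies of each other: the chi-square per degree of freedom over genes was 27.7 between the wild-type libraries and 54.3 between those labelled knockout, where sampling noise alone gives about 1. All 35275 rows name a gene.

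Counts were compared with edgeR 4.0.16 in R 4.3.3: genes with enough counts by filterByExpr (17536), TMM normalization, the quasi-likelihood F test with the group as the only term and 2 residual degrees of freedom, two-sided, and Benjamini-Hochberg adjusted p under 0.05. CPM values are TMM-scaled, with the SD over the 2 libraries of a group. Log2 fold changes are labelled knockout over wild type, and each SE is the size of the log2 fold change divided by the square root of its F value. Where a group held 1 to 3 reads of a gene, the ratio of the totals is given with an exact binomial 95% interval. Such intervals cover counting error only.

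In simulated data with the real means, library sizes and dispersions, 17536 genes were tested and 50 changed genes were drawn at each fold size. The edgeR test recovered 1 of 50 genes changed 1.5-fold, 17 of 50 changed 2-fold, 35 of 50 changed 3-fold and 38 of 50 changed 4-fold, and called 31 unchanged genes. Those 31 were a larger share of its calls than an adjusted p under 0.05 allows, so the threshold was not kept in this simulation.

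The 34 gene lists (retinal cell types, other eye tissues, photoreceptor functions, stress and immune responses, metabolism and reference genes), the tests, most alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 on log-CPM at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Camera asks whether a list's genes differ from the other genes, and fry whether they move on balance in a single direction. In a simulated set of lists, camera with the preset correlation called the 1 shifted list and 0 of 33 others, whereas the estimated correlation did not call the shifted list. Fry did not call it either, and called 1 of 33 others. The simulated genes were drawn independently of each other, which is close to what the preset assumes. In the data the estimated correlation was 0.638 in the ribosomal, 0.535 in the gliosis and 0.254 in the cone list. It was 0.04 in the ganglion cell and 0.037 in the rod list. The simulation therefore cannot tell how often the preset test calls unshifted lists of correlated genes. The named genes are Kmt2e, then fixed photoreceptor genes, among them Opn1sw, Opn1mw, Crx, Nrl and Nr2e3, whatever their result, then the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap, with a mean of at least 1 CPM and a named, non-pseudogene symbol, then up to 4 members past the threshold of each list described, by adjusted p, or the 2 most abundant members where none passed. Not every gene that the rule takes is described in the text.

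Alternatives were DESeq2 size factors and upper-quartile scaling in edgeR, no filter and a filter of 1 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the edgeR likelihood ratio test, the replicate number as a block, each library left out in turn (a library left alone in its group was assumed to vary like the other group), removal of the 20 most abundant genes, limma on log2(FPKM + 1) for genes with a mean of at least 1 FPKM, and stricter thresholds. A fit without genes of the X and Y chromosomes, a fit with the Y-linked signal as a covariate and upper-quartile scaling for the list tests were added after seeing the data.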

Results

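The study compared the transcriptome of wild-type mouse retina with that of retina from mice labelled Mll5 (Kmt2e) knockout at postnatal day 18, when photoreceptors are close to mature. Kmt2e is a SET and PHD domain protein of the family named for H3K4 methyltransferases. There were 2 libraries per genotype, with 37744857 to 49577833 counted reads each. On the first principal component of log-CPM, which held 70.3% of the variance, the wild-type libraries lay at -40.3 and -55.2 and the libraries labelled knockout at 72.3 and 23.2.

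Kmt2e reads were not lower in the libraries labelled knockout. The gene (ENSMUSG00000029004, mm10 chromosome 5, 23434441 to 23504235, plus strand) had 11593 and 9749 reads in wild-type replicates 1 and 2, against 15536 and 12245 in labelled-knockout replicates 1 and 2. The scaled level was 241 ± 17.5 CPM in wild type and 344 ± 32.9 CPM in the libraries labelled knockout (SD, n = 2), a log2 fold change of 0.52 (SE 0.13, edgeR adjusted p = 0.0556). Over the alternatives the adjusted p of Kmt2e ran from 0.00629 to 0.318, with the value higher in the libraries labelled knockout in each. A count over the whole gene includes reads of exons outside a deleted part, and the labels do not say which part was deleted. This value therefore does not check the genotype. All directions below rest on the libraries as labelled.

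Retinas labelled knockout had less of many cone transcripts and of some transcripts of rods and inner retinal cells, and more of some transcripts of gliosis and of ribosomal proteins. Of 17536 genes tested, 1793 changed (edgeR adjusted p under 0.05): 868 were higher and 925 lower. At least 2-fold changes were seen in 303 higher and 591 lower genes, and 1573 of the changed genes were protein-coding. In 64.8% of the tested genes the 2 groups did not overlap, where chance gives 33.3% for a single gene. Genes that vary together can raise this share for any split of the libraries into pairs. The share is therefore no separate evidence of a difference between the groups. Of the changed genes 48.4% were higher, a share of 37.4% with upper-quartile scaling and 39.0% in the limma fit of FPKM. The number of changed genes depended on the library left out. Such a fit takes its spread only from the group that keeps 2 libraries. The pair labelled knockout differed more than the wild-type pair (chi-square per degree of freedom 54.3 against 27.7). Without replicate 1 of wild type edgeR called 1 gene, Xist, which lies outside the rule for named genes and was named after its values were seen (3075 genes at an unadjusted p under 0.05). Without replicate 2 of wild type it called 0 (2789 genes at an unadjusted p under 0.05), and without labelled-knockout replicate 2 it called 5664. Although the labels give female mice, Y-linked transcripts summed to 336 CPM in wild-type replicate 2 and 93.8 CPM in labelled-knockout replicate 2, against 0.26 and 0.11 CPM in the replicates numbered 1. With the Y-linked signal of the libraries as a covariate, an alternative chosen after seeing the data, 198 genes were called.

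**Figure D1:**
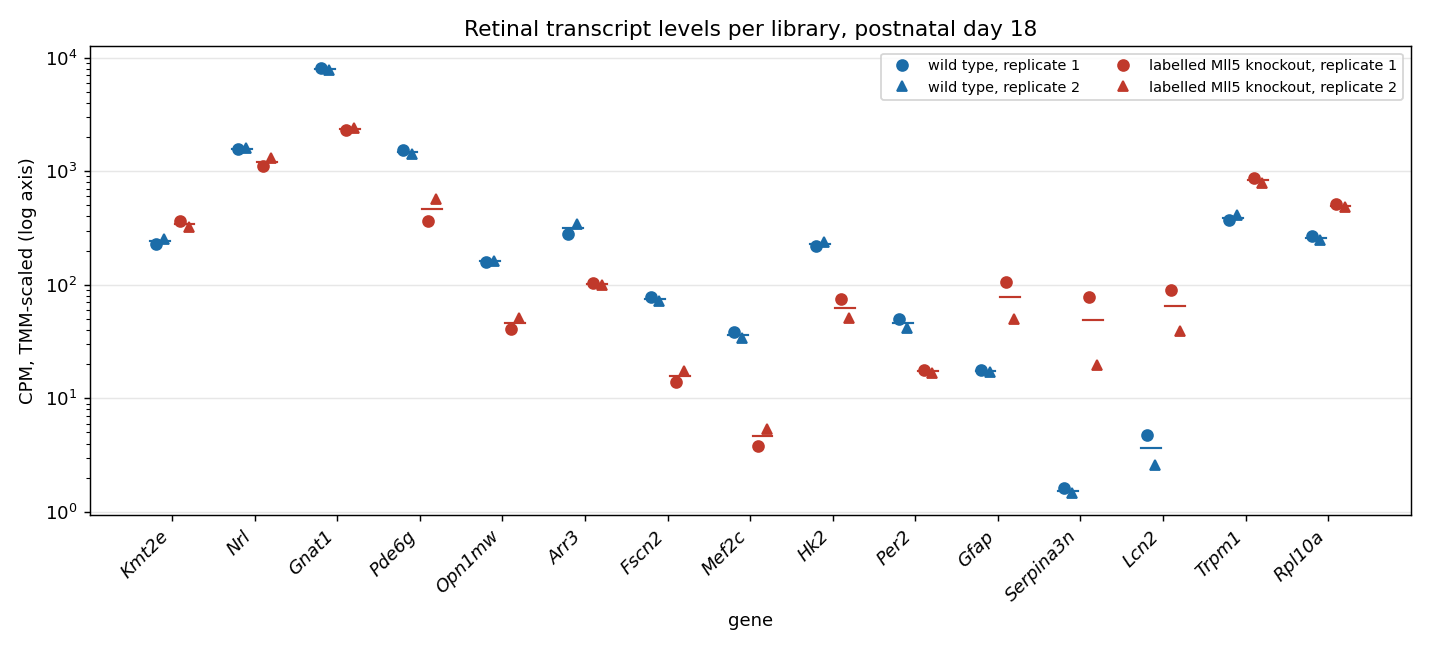
Each point is the TMM-scaled CPM (log axis) of a gene in 1 library, blue for wild type and red for the libraries labelled knockout, with circles for replicate 1, triangles for replicate 2 and bars for the group means. Gnat1 averaged 7967 CPM in wild type and 2363 CPM in the libraries labelled knockout, whereas Kmt2e averaged 241 and 344 CPM.

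Cone transcripts fell in part. Of 16 tested genes of cone phototransduction and cone markers, 10 were lower and 0 higher in the libraries labelled knockout (12 lower when adjusted over the list alone). The M-opsin gene Opn1mw went from 161 ± 1.96 to 45.9 ± 7.08 CPM (SD, n = 2; log2 fold change -1.81, SE 0.14, edgeR adjusted p = 0.0143). Cone arrestin Arr3 went from 314 ± 44.9 to 101 ± 3.07 CPM (log2 fold change -1.63) and cone transducin Gnat2 from 146 ± 17.9 to 59.6 ± 10.4 CPM (-1.29). The S-opsin gene Opn1sw went from 361 ± 81.5 to 143 ± 40.8 CPM (-1.34, edgeR adjusted p = 0.0343). The exchanger gene Slc24a2 had a log2 fold change of -0.81. The list lay below the other genes with the preset correlation (camera adjusted p = 1.04e-04), and its adjusted p was 0.728 with an estimated correlation.

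Rod transcripts fell in part. Of 21 tested rod phototransduction genes, 6 were lower and 0 higher (11 lower when adjusted over the list alone; camera adjusted p = 9.16e-04, adjusted p = 0.728 with an estimated correlation). Rod transducin Gnat1 fell from 7967 ± 282 to 2363 ± 72.7 CPM (SD, n = 2; log2 fold change -1.75, SE 0.13, edgeR adjusted p = 0.0143). The phosphodiesterase subunit genes Pde6g and Pde6a had log2 fold changes of -1.67 and -0.88, and the rod exchanger gene Slc24a1 one of -0.61. Of 18 tested outer segment genes 5 were lower and 0 higher (7 lower when adjusted over the list alone; camera adjusted p = 0.00649, adjusted p = 0.728 with an estimated correlation). Among them were the actin-bundling gene Fscn2 (74.6 ± 4.19 to 15.8 ± 2.45 CPM, log2 fold change -2.24) and the protocadherin gene Pcdh15 (-1.13).

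The transcription factors that specify photoreceptors showed no common shift. In wild type and the libraries labelled knockout, Crx was at 1163 ± 73.2 and 1306 ± 117 CPM (SD, n = 2; log2 fold change 0.17, SE 0.13, edgeR adjusted p = 0.417). The rod factor Nrl was at 1577 ± 19.4 and 1207 ± 129 CPM (-0.39, SE 0.13, edgeR adjusted p = 0.111) and was called lower without labelled-knockout replicate 2 (edgeR adjusted p = 0.025). Nr2e3 was at 684 ± 26.1 and 668 ± 193 CPM (-0.03, SE 0.21, edgeR adjusted p = 0.928), and its direction turned without wild-type replicate 1 (0.01) or labelled-knockout replicate 1 (0.24). Of the 18 factors tested 1 was higher and 2 lower (1 and 3 when adjusted over the list alone; camera adjusted p = 0.841). Samd7, a repressor in rods, rose (log2 fold change 1.17), while Mef2c fell from 36.1 ± 3.02 to 4.62 ± 1.11 CPM (-2.97, edgeR adjusted p = 0.0143) and Ankrd33 fell with a log2 fold change of -2.21.

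At the photoreceptor ribbon synapse 3 of 21 tested genes were lower and 0 higher (4 lower when adjusted over the list alone; camera adjusted p = 0.0339, adjusted p = 0.728 with an estimated correlation). They were the complexin gene Cplx4 (-1.23), the calcium channel gene Cacna1f (-0.74) and Cabp4 (-0.91). The call of that list ended without wild-type replicate 1 (camera adjusted p = 0.0628), wild-type replicate 2 (0.074) or labelled-knockout replicate 2 (0.193). Of 25 genes of the cilium and intraflagellar transport 1 was higher and 4 lower (1 and 6 when adjusted over the list alone; camera adjusted p = 0.0823). This list was called lower with the filter of at least 1 CPM in 2 libraries (camera adjusted p = 0.0491) and without labelled-knockout replicate 2 (0.0424). Arl6 rose (0.85), a call that limma-voom ended (adjusted p = 0.051). Among the lower genes were the Bardet-Biedl genes Ttc8 (-0.78) and Bbs4 (-0.63) and the kinesin gene Kif17 (-0.89). Of 45 mouse counterparts of human retinitis pigmentosa genes 1 was higher (Dhdds, 1.07) and 7 lower (the same counts when adjusted over the list alone; camera adjusted p = 0.113). Fam161a (-0.84) and Fscn2 were among those that fell.

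**Figure D2:**
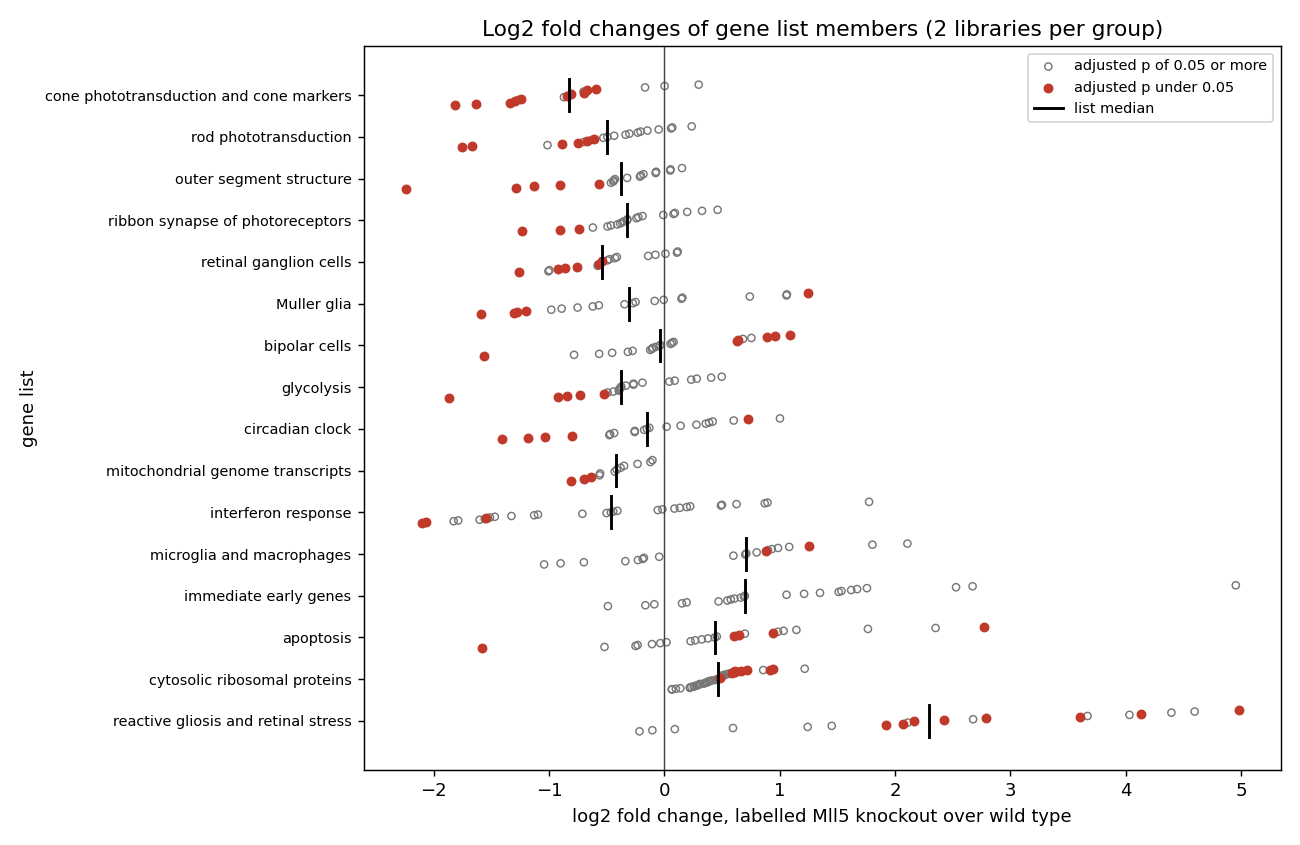
Each point is the log2 fold change of a list member, labelled knockout over wild type (2 libraries per group), filled where the edgeR adjusted p was under 0.05, with a bar at the list median, for 16 of the 34 lists. The medians run from -0.82 in the cone list to 2.29 in the gliosis list.

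Stress and gliosis genes rose in part, and stood higher in labelled-knockout replicate 1 than in replicate 2. Of 20 genes of reactive gliosis and retinal stress 8 were higher and 0 lower (16 higher when adjusted over the list alone; camera adjusted p = 5.33e-05, adjusted p = 0.728 with an estimated correlation). Gfap, the intermediate filament of reactive glia, rose from 17.4 ± 0.61 to 77.9 ± 40.1 CPM (SD, n = 2; log2 fold change 2.16, SE 0.35, edgeR adjusted p = 0.0285). Serpina3n rose from 1.53 ± 0.11 to 48.6 ± 40.7 CPM (4.98, SE 0.70, edgeR adjusted p = 0.0241) and Lcn2 from 3.66 ± 1.51 to 64.8 ± 35.9 CPM (4.13, SE 0.50, edgeR adjusted p = 0.0215). Complement C4b, whose reads can be shared with its copy C4a, rose by 2.42 on the log2 scale. In the labelled-knockout libraries, replicate 1 held 77.4 and replicate 2 held 19.8 CPM of Serpina3n, and over the list the median log2 ratio of replicate 1 to replicate 2 was 1.41. The immediate early genes were split in the same direction, with a median log2 ratio of 1.18 between those replicates. None of the 23 immediate early genes passed the edgeR threshold (0 higher, 0 lower, also when adjusted over the list alone). The most abundant were Egr1 (log2 fold change 0.15, SE 0.39) and Btg2 (-0.49, SE 0.14), and the direction of Egr1 turned without labelled-knockout replicate 1 (-0.59) or wild-type replicate 2 (-0.05). Btg2 was called lower with no filter (adjusted p = 0.0303), DESeq2 (0.0375), the likelihood ratio test (0.0402), the replicate block (0.0302) and without labelled-knockout replicate 2 (0.00758), where Egr1 was called higher (0.0265). Their list was called higher by camera (adjusted p = 0.00864, and adjusted p = 0.735 with an estimated correlation), a call that ended without labelled-knockout replicate 1 (0.0887).

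Further groups tied to immunity and cell death moved in different directions. Of 20 genes of microglia and macrophages 2 were higher, the complement gene C1qc (log2 fold change 0.88) and the adaptor gene Tyrobp (1.25), and 0 lower (8 higher when adjusted over the list alone; camera adjusted p = 0.0294, adjusted p = 0.728 with an estimated correlation). The call of the list ended without wild-type replicate 2 (0.0532) or labelled-knockout replicate 2 (0.182), and upper-quartile scaling ended the calls of both genes (edgeR adjusted p = 0.0534 and 0.0536). Of 29 interferon response genes 3 were lower and 0 higher (1 higher and 10 lower when adjusted over the list alone; camera adjusted p = 0.0209, adjusted p = 0.728 with an estimated correlation). Ifit3 (-2.07), Isg15 (-2.10) and Ifi27 (-1.55) fell, and the call of the list ended without labelled-knockout replicate 2 (0.155). Of 23 apoptosis genes 4 were higher and 1 lower (7 and 1 when adjusted over the list alone; camera adjusted p = 0.0111, adjusted p = 0.728 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose from 8.32 ± 1.03 to 56.6 ± 29.0 CPM (SD, n = 2; log2 fold change 2.77). The p53 ligase gene Mdm2 rose by 0.64 on the log2 scale. Of 25 cell cycle genes 2 were higher, the inhibitor genes Cdkn1c (0.96) and Cdkn1b (0.47), and 0 lower (3 and 0 when adjusted over the list alone; camera adjusted p = 0.149). The cell cycle list was called higher without labelled-knockout replicate 1 (camera adjusted p = 0.0261). Upper-quartile scaling and the limma fit of FPKM ended the call of Cdkn1b (adjusted p = 0.0609 and 0.0702). Heat shock and unfolded protein genes had 1 of 25 higher, Atf4 (0.71), and 0 lower (the same when adjusted over the list alone; camera adjusted p = 0.94), and their median, -0.04, was opposite in sign to the test.

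Among inner retinal cells, ganglion cell genes fell in part. Of 20 tested, 6 were lower and 0 higher (13 lower when adjusted over the list alone; camera adjusted p = 3.32e-04, adjusted p = 0.728 with an estimated correlation). The surface glycoprotein gene Thy1 went from 220 ± 8.14 to 130 ± 3.41 CPM (SD, n = 2; log2 fold change -0.76, edgeR adjusted p = 0.0233). The nicotinic receptor gene Chrnb3 had a log2 fold change of -0.86, Tusc5 one of -1.26, and the glutamate transporter gene Slc17a6 one of -0.54. Bipolar cell genes went both ways, with 5 of 22 higher and 1 lower (7 and 1 when adjusted over the list alone; camera adjusted p = 0.55). The ON-bipolar channel gene Trpm1 rose from 391 ± 30.2 to 833 ± 66.1 CPM (1.09, SE 0.13, edgeR adjusted p = 0.0215). Lhx4 rose by 0.96 and Isl1 by 0.63 on the log2 scale, and Sebox fell (-1.57). The list's median was -0.04 although its test pointed upward. Of 20 Muller glia genes 1 was higher and 4 lower (1 and 6 when adjusted over the list alone; camera adjusted p = 0.213). The water channel gene Aqp4 fell from 81.9 ± 4.51 to 33.8 ± 6.94 CPM (-1.28). Abca8a (-1.59) and the retinaldehyde-binding protein gene Rlbp1 (-1.20) were lower, and Crym rose (1.25). Amacrine cell genes had 3 of 19 lower, Slc17a8 (-1.20), Calb2 (-0.95) and Slc6a9 (-0.62), and 0 higher (4 lower when adjusted over the list alone; camera adjusted p = 0.579). Calb1 (-0.60) was the only 1 of 12 horizontal cell genes past the threshold (2 lower when adjusted over the list alone; camera adjusted p = 0.94). Of 26 long neuronal and axon guidance genes Slit2 was higher (0.46) and Dlg2 lower (-0.45), with 0 past the threshold when adjusted over the list alone (camera adjusted p = 0.518). Upper-quartile scaling and the limma fit of FPKM ended the call of Slit2 (adjusted p = 0.0613 and 0.0676).

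Cytosolic ribosomal protein genes rose in part. All 49 had a log2 fold change above 0, with a median of 0.47, and 9 passed the threshold (23 when adjusted over the list alone; camera adjusted p = 5.35e-08, adjusted p = 0.728 with an estimated correlation). Rpl10a went from 260 ± 13.7 to 499 ± 25.7 CPM (SD, n = 2; log2 fold change 0.94, SE 0.12, edgeR adjusted p = 0.0215). Rps14, Rps19 and Rpl22 rose by 0.92, 0.72 and 0.67 on the log2 scale. Reads of such genes can be shared with pseudogenes. Among 17 housekeeping reference genes the elongation factor gene Eef1a1 was higher (0.63) and 0 were lower (1 and 1 when adjusted over the list alone; camera adjusted p = 0.771). The limma fit of FPKM ended the call of Eef1a1 (adjusted p = 0.0867). Of 36 nuclear-encoded oxidative phosphorylation genes 3 were higher, Cox6a1 (0.83), Sdhd (0.72) and Ndufs3 (0.52), and 0 lower (the same counts when adjusted over the list alone; camera adjusted p = 0.0189, adjusted p = 0.735 with an estimated correlation). The call of the list ended without wild-type replicate 1 (0.162) or labelled-knockout replicate 2 (0.755), and that of Ndufs3 with upper-quartile scaling (0.0632) or in the limma fit of FPKM (0.0756). The transcripts of the mitochondrial genome lay on the other side. All 12 tested had a log2 fold change below 0, and 3 fell, mt-Nd2 (-0.81), mt-Nd6 (-0.70) and mt-Nd5 (-0.64), with 0 higher (5 lower when adjusted over the list alone; camera adjusted p = 0.00864, adjusted p = 0.728 with an estimated correlation).

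Glycolytic genes fell in part, with 5 of 22 lower and 0 higher (1 higher and 9 lower when adjusted over the list alone; camera adjusted p = 0.0226, adjusted p = 0.735 with an estimated correlation). Hexokinase 2, Hk2, which photoreceptors use for aerobic glycolysis, went from 229 ± 15.95 to 62.7 ± 17.3 CPM (SD, n = 2; log2 fold change -1.87, SE 0.20, edgeR adjusted p = 0.0189). The lactate transporter genes Slc16a1 and Slc16a3 had log2 fold changes of -0.84 and -0.92, and aldolase C, Aldoc, one of -0.73. The call of the list ended without wild-type replicate 2 (0.113) or labelled-knockout replicate 2 (0.324), and with the Y-linked covariate (0.0511). Of 21 circadian clock genes 1 was higher and 4 lower (2 and 6 when adjusted over the list alone; camera adjusted p = 0.573). Arntl rose from 101 ± 3.41 to 167 ± 8.00 CPM (0.73, edgeR adjusted p = 0.0251). Per2 fell from 45.7 ± 5.69 to 17.3 ± 0.84 CPM (-1.40, edgeR adjusted p = 0.0185), as did the output gene Dbp (-0.80) and the dopamine receptor gene Drd4 (-1.04), which cycles in photoreceptors. Of 22 H3K4 methyltransferases and their partners and opponents 3 were higher, the demethylase genes Kdm1a (0.71) and Kdm5a (0.56) and Setd5 (0.62), and 1 was lower, Kmt2a (-0.83). Adjusted over the list alone there were 6 and 1 (camera adjusted p = 0.0189, adjusted p = 0.728 with an estimated correlation), and the call of the list ended without wild-type replicate 2 (0.0532).

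Markers of other eye tissues differed between single libraries as well as between groups. Of 23 genes of the visual cycle and pigment epithelium 2 were lower, the photoreceptor dehydrogenase gene Rdh8 (-1.42) and Rlbp1, and 0 higher (the same when adjusted over the list alone; camera adjusted p = 0.00864, adjusted p = 0.728 with an estimated correlation). The median member of that list was higher in wild-type replicate 2 than in replicate 1 by 0.89 on the log2 scale, and the call ended without replicate 2 of wild type (0.0716). Of 18 lens genes 2 were lower, the crystallin genes Crygd (-2.44) and Crygc (-2.16), which have near-identical copies, and 0 higher (4 lower when adjusted over the list alone; camera adjusted p = 0.0172, adjusted p = 0.735 with an estimated correlation). Lens transcripts were scarcest in labelled-knockout replicate 1, with a median log2 ratio to replicate 2 of -1.39. Without that library the list's median was 0.11 and the direction of its test turned (0.466), and without wild-type replicate 2 the call ended (0.0716). Endothelial and pericyte genes had 2 of 19 lower, Ly6c1 (-1.27) and Myh11 (-1.58), and 0 higher (4 lower when adjusted over the list alone; camera adjusted p = 0.0485, adjusted p = 0.735 with an estimated correlation). That call ended with upper-quartile scaling (0.065) and without wild-type replicate 2 (0.371) or either library labelled knockout (0.0906 and 0.0929), and with the Y-linked covariate (0.197). Of 11 genes of cornea, iris and surface epithelium Col3a1 was lower (-1.62) and 0 were higher (the same when adjusted over the list alone; camera adjusted p = 0.579). Of 7 genes of extraocular muscle Pvalb, which neurons also express, was lower (-2.38), with 2 lower when adjusted over the list alone (camera adjusted p = 0.214). Of 12 genes of astrocytes and optic nerve Gfap was the 1 past the threshold (1 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.55). None of 11 blood genes passed the edgeR threshold, also when adjusted over the list alone (camera adjusted p = 0.94). The most abundant, Hbb-bs and Hba-a1, which have near-identical copies, had log2 fold changes of 0.11 (SE 0.42) and -0.06 (SE 0.49), and the direction of each turned with single libraries left out. Hbb-bs was called higher without labelled-knockout replicate 2 (edgeR adjusted p = 0.0391).

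The largest rises by the rule included chemokine and acute-phase genes. The neutrophil chemokine gene Cxcl1 had 1 read in the wild-type libraries together and 1068 in those labelled knockout, a ratio of 1130 (exact binomial 95% interval 202 to 44680), of which 1008 reads came from replicate 1 and 60 from replicate 2. The monocyte chemokine gene Ccl2 stood at 0.068 ± 0.013 and 8.76 ± 10.1 CPM (SD, n = 2; log2 fold change 6.96, SE 1.36, edgeR adjusted p = 0.0383). The acute-phase gene Saa3 stood at 0.072 ± 0.065 and 3.64 ± 3.29 CPM (5.51), and Steap4 at 0.52 ± 0.11 and 16.2 ± 15.0 CPM (4.95). Limma-voom ended the calls of Cxcl1 (adjusted p = 0.102), Ccl2 (0.11), Saa3 (0.0606) and Steap4 (0.0637), and the limma fit of FPKM those of Cxcl1 (0.0894), Ccl2 (0.0773) and Steap4 (0.0548). The lymphocyte co-receptor gene Cd8a (4.58) and the inhibitory receptor gene Lilrb4 (4.08) rose at low levels, Cd8a to 1.96 ± 0.53 CPM. Serpina3n and Lcn2 were also among these rises. The largest falls were Sh2d1a, an adaptor of lymphocyte signalling, from 4.04 ± 0.39 to 0.1 ± 0.15 CPM (log2 fold change -5.28, SE 0.85, edgeR adjusted p = 0.0278), and the adaptor gene Sla2 (-4.57, SE 0.77). Sla2 was at -3.455 without wild-type replicate 1 and at -5.177 without wild-type replicate 2. The largest falls also held the antisense RNA Ube4bos1 (-3.84), the coagulation factor gene F5 (-3.82), the histone variant gene H2afb1 (-3.64), the matrix gene Fbln1 (47.7 ± 22.8 to 3.88 ± 4.05 CPM, -3.63), Slc17a4 (-3.59) and Traf3ip3 (10.1 ± 1.51 to 0.88 ± 0.17 CPM, -3.52). Ube4bos1 overlaps Ube4b on the other strand and H2afb1 has close copies, so their reads carry that uncertainty.

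With the preset correlation, 18 of the 34 lists passed the camera threshold, 7 upward and 11 downward. With the estimated correlation 0 did (smallest unadjusted p = 0.0771 over the lists), and with fry 0 did (smallest adjusted p = 0.0649). Neither of these tests called the shifted list of the simulation, so their lack of calls does not show that the lists did not move. The interferon list, with an estimated correlation of -0.007, had an unadjusted camera p of 0.00862 with the preset and 0.097 with the estimate. Correlation between genes therefore does not alone account for the lost calls. The calls of the ribosomal, gliosis, cone, ganglion cell, rod, outer segment, mitochondrial and apoptosis lists held with each library left out in turn.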

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

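The tests in this part were chosen after their results were seen. The deposited group FPKM columns hold reads of libraries that entered no comparison. In the tables of replicate 1 the group value equals the library's own FPKM for 100% of genes. In the tables of replicate 2 it equals the mean of that library and a further library whose reads come out whole, within 0.05 reads, for 100% of 21536 genes in wild type and of 21567 genes in knockout. The recovered totals were 38330470 reads behind the wild-type column and 36533929 reads behind the knockout column, and neither further library entered a comparison of the groups.

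Scaled to library totals, Gnat1 stood at 2162 CPM behind the wild-type column and 6075 CPM behind the knockout column, Opn1mw at 49.5 and 163 CPM, and Arr3 at 107 and 251 CPM, whereas Kmt2e stood at 267 and 339 CPM. Of the gliosis genes Gfap stood at 24.9 and 70.1 CPM, Serpina3n at 4.70 and 2.98 CPM and Lcn2 at 11.4 and 2.60 CPM. Of the 1793 changed genes, 31.6% had the library behind the knockout column on the knockout side of that behind the wild-type column, but this sets 1 library against 1, and genes that vary together are not replicates, so whether the difference between the groups carries over stays open. An exchange of both further libraries would turn nearly all changed genes, where 68.4% were turned, and it stays open only because 1 library is set against 1. On the knockout side lay 0 of 6 changed rod, 2 of 10 cone and 6 of 8 gliosis members. The library behind the wild-type column stood at a median of 0.517 of the way from wild type (0) to the labelled-knockout level (1). The median for the library behind the knockout column was 0.259. A plain exchange would put the first median near 1 and the second near 0, which these values did not reach. Batch, age and time of collection of the further libraries were not tested, nor was any biological explanation, since the design puts these libraries in no group.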

How the results depend on the processing

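The fits without X and Y genes and with the Y-linked covariate, and upper-quartile scaling for the list tests, were chosen after seeing the data. Of the 1793 changed genes, 0 had the opposite direction in any alternative in which they were measured. In all 1793 the groups did not overlap, which leaves other fits of the same counts little room to turn a direction. The count of 0 is therefore no separate check. With 2 libraries per group the self-test recovered 1 of 50 genes changed 1.5-fold, so small changes can be missed. Far fewer genes were changed in the self-test than in the data, which makes its adjusted threshold stricter, so its rate does not carry over. The self-test also called 31 unchanged genes, a larger share of its calls than an adjusted p under 0.05 allows. The share of such calls among the 1793 changed genes is not known. In the data 1589 of the 1793 changed genes were at least 1.5-fold apart, and the others less. The number of changed genes was 3879 (1927 higher, 1952 lower) with no filter, 3529 (1888 and 1641) with DESeq2, 3524 (1655 and 1869) with the likelihood ratio test, 198 (76 and 122) with the Y-linked signal as a covariate, which leaves 1 residual degree of freedom, and 0 (0 and 0) at an adjusted p under 0.01. With each library left out in turn it ranged from 0 to 5664 (0 to 2890 higher, 0 to 2774 lower). Of 111 named genes besides Kmt2e, 78 lost their call with the covariate. A fit without a wild-type library takes its spread from the 2 libraries labelled knockout alone. Without a library labelled knockout, the spread comes from the wild-type pair alone. The libraries labelled knockout differed more from each other (chi-square per degree of freedom 54.3 against 27.7). Fewer calls without a wild-type library therefore do not show that the differences rested on that library. The replicate block gave 4127 genes (1985 and 2142). The labels speak of 2 pairs of mice but do not say that the replicate number marks a pair. The second principal component held 19.9% of the variance. On it the replicates numbered 1 lay at 32.28 (wild type) and 18.86 (labelled knockout), and those numbered 2 at -14.35 and -36.79. The correlation of the deviations of same-numbered libraries was 0.373. Both observations rest on 2 pairs, so a factor shared by replicate number stays possible and pairing was not established. Kmt2e was past the threshold with no filter (0.528), DESeq2 (0.538), the likelihood ratio test (0.517) and the replicate block (0.516) and without labelled-knockout replicate 2 (0.620), and ranged from 0.419 to 0.620 with a library left out. The number of lists past the threshold was 0 with the estimated correlation, 0 with fry and 11 to 16 with a library left out.

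Among results past the threshold the direction of the lens list turned, and the median of the oxidative phosphorylation list was -0.036 without labelled-knockout replicate 2. The other turns were in results not past it. Hbb-bs was at -0.016 with limma-voom, -0.01 with the replicate block, -0.081 in the limma fit of FPKM and -0.194 with the covariate, and Egr1 at -0.021 in the limma fit of FPKM and -0.137 with the covariate. The blood list had a median of 0.071 with fry, whose direction turned, and -0.476 with the covariate. The heat shock list had medians of -0.038 with fry, -0.113 with upper-quartile scaling, -0.054 with at least 1 CPM in 2 libraries and -0.03 with the replicate block, and the horizontal cell list -0.002 with fry and -0.018 with at least 1 CPM in 2 libraries. With a library left out in turn, Nr2e3 ranged from -0.354 to 0.237, Hbb-bs from -0.694 to 0.629, Hba-a1 from -0.914 to 0.473 and Egr1 from -0.592 to 0.651. The list medians ranged from -0.4 to 0.323 (astrocytes), -0.971 to 0.629 (blood), -0.157 to 0.074 (heat shock), -0.029 to 0.111 (horizontal cells), -2.752 to 0.107 (lens) and -0.083 to 0.038 (photoreceptor transcription factors). For these the cause was not tested.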

Other observations

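The gene families, single genes and tests in this part were chosen after the values were seen. Of 75 tested potassium channel subunit genes 10 were lower and 1 higher (13.3% lower against 5.24% of the others), with 11 lower under DESeq2 size factors and 12 under upper-quartile scaling. Kcnj14, an inward rectifier, went from 374 ± 25.2 to 92.5 ± 16.9 CPM (SD, n = 2; log2 fold change -2.02, edgeR adjusted p = 0.0153), and Kcnv2, a photoreceptor subunit also in the cone list, from 479 ± 53.1 to 294 ± 19.2 CPM (-0.70). Collagen chain genes had 8 of 44 lower and 1 higher (18.2% lower against 5.24%), with 8 and 9 lower under those scalings. Since both families were picked for these values, no test of them is given. Among single genes, Nxnl1, which encodes a rod-derived cone viability factor, went from 287 ± 4.67 to 90.6 ± 31.1 CPM (-1.66, edgeR adjusted p = 0.0243) and Vtn from 452 ± 61.7 to 87.2 ± 13.7 CPM (-2.37, edgeR adjusted p = 0.0143), while Glp2r rose from 150 ± 59.2 to 731 ± 17.1 CPM (2.29, edgeR adjusted p = 0.0215).

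No biological process term of the deposited annotation was enriched. Of 978 terms, 0 passed among the 400 higher genes with a term (smallest hypergeometric adjusted p = 1) and 0 among the 407 lower (0.386). Near Kmt2e, 16 of 151 tested genes within 10 Mb changed (10.6%), against 1777 of 17384 elsewhere (10.2%; Fisher two-sided p = 0.892).

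Although the labels give female mice, Xist had 88081 and 12 reads in wild-type replicates 1 and 2 and 74406 and 63647 in labelled-knockout replicates 1 and 2, and the Y-linked gene Eif2s3y had 2, 6116, 2 and 1820. RNA of wild-type replicate 2 mixed into labelled-knockout replicate 2 would leave no gene below the Y-linked share of 27.9%, and 80 genes lay below it. Their limits cover counting error only, and the Y-linked genes themselves ran from 23.9% (Ddx3y) to 29.6% (Eif2s3y). Fbln1 and Mef2c lay below even the lowest of these shares. Fbln1 had 63.9 CPM in wild-type replicate 2 and 6.74 CPM in labelled-knockout replicate 2, and Mef2c 33.9 and 5.40 CPM (TMM-scaled). The 80 genes argue against such mixing, with 1 library on either side. Sex as the main difference between the libraries is argued against by the spread between the libraries nearly free of Y-linked reads, 1 of each group. That spread was 2.00 times that between the wild-type libraries (SD of log2 ratios 0.68 and 0.34). A male among the pooled eyes of labelled-knockout replicate 2 may account for its Y-linked reads and stays open. Of 2 eyeballs mixed in equal amounts, 1 from a male would give equal male and female shares, and the Y-linked share of 27.9% lies below that. Whether the amounts were equal was not tested. Xist of labelled-knockout replicate 2 stood at 97.2% of the mean of replicates 1 (1777 and 1671 CPM), where 72.1%, the complement of the Y-linked share, was expected. Only the further library behind the knockout column shows that Xist varies by more than that gap. That library stood at 160% (2755 CPM) without Y-linked signal above 0.055 CPM a gene. The further library behind the wild-type column held both Xist (359 CPM) and Eif2s3y (135 CPM). Sex of the animals stays open as a part of the difference. The 198 genes called with the Y-linked covariate do not decide this, since the covariate cannot be told apart from other differences between single libraries. That fit leaves 1 residual degree of freedom, but the replicate block adds 1 term as well and gave 4127 genes. The lost degree of freedom alone therefore does not account for the fewer calls. Some log2 fold changes stayed about as large with the covariate, such as -1.42 for Opn1sw and 1.13 for Trpm1. Others shrank, such as that of Ifi27 from -1.55 to -1.27. Without X and Y genes 1780 genes were called.

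Of the clock genes, Ciart (-1.18, edgeR adjusted p = 0.0376) was past the threshold beside Per2, Dbp, Drd4 and Arntl, and the clock list was not called. Of 16 genes listed by arm, most of them not past the threshold, 13 had log2 fold changes on opposed sides: 8 of 10 output genes lay below 0 (Per1 and Nr1d2 did not) and 5 of 6 genes of the Arntl arm above 0 (Clock did not). In replicate 2 the 5 clock genes changed by 72.0% to 139% (median 104%) of their change in labelled-knockout replicate 1. The 8 gliosis genes changed by 20.01% to 50.6%. These are shares of CPM, where a fall is bounded by the wild-type level and a rise is not. Of the 5 clock genes 4 fell and only Arntl rose (84.2%), while the 8 gliosis genes rose, so the shares cannot be compared directly. A cause that grows with the stress response of labelled-knockout replicate 1 therefore stays open, as does a response that both libraries share equally. Another time of day at tissue collection is a candidate explanation that the 13 genes go with, and the labels give no time. An effect of the genotype on the clock was not tested and stays open.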
